A study of Papio anubis with 8 samples.

How the data were processed

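Polyadenylated RNA was measured in 8 libraries of baboon carotid artery endothelial cells, 4 from a planar and 4 from a micropatterned polyurethane substrate. Per the labels' protocols, the cells were grown in a commercial endothelial medium with 8% added serum, total RNA was column-purified, samples with an RNA integrity number of at least 9.9 were taken, and 300 ng went into a strand-preserving mRNA library kit. The authors deposited 1 table of raw read counts per gene, not normalised, for 29476 Ensembl gene identifiers. Per the submitters' processing notes, STAR 2.7.10b, edgeR 3.28.0 and bcl2fastq were used, without a stated role or order. The read counter, its strand setting, the treatment of reads that map to several places, the genome build and the annotation release are not given in the sources used here. Reads shared by near-identical genes or overlapping genes can therefore have been split or dropped in a way that cannot be recovered from the counts. Each column of the table matched the title of 1 sample, and 0 columns were left unused.

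No symbol could be attached to any gene. The table holds identifiers only, and 0 of them matched the reference table used here, which lists 39274 baboon genes without Ensembl identifiers. For this reason the 37 gene lists fixed before the data were examined (flow-responsive, inflammatory, haemostatic, cytoskeletal, junctional, cell cycle and metabolic genes, and markers of other cell types) could not be tested, and 0 of them have a result. The planned rule for named genes, the 10 largest changes per direction among called genes with a symbol and a mean of at least 1 CPM, with further genes named by symbol, was reduced to the first 2 identifiers per direction. Gene positions, GC content and lengths were not used here.

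Genes were kept with the default expression filter of edgeR, which left 13740 genes holding 99.97% of all reads; 9687 identifiers had no read in any library. Counts were scaled by TMM factors, which lay between 0.994 and 1.008. The comparison used edgeR 4.0.16 in R 4.3.3, with robust quasi-likelihood dispersion, group as the only term and all 8 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 changes were taken as the change divided by the square root of its F statistic. CPM are counts relative to the TMM-scaled library size. Confidence intervals of fold changes came from limma 3.58.1 after voom. Log2 CPM with a prior count of 2 was used for principal components and for the share of squared distance explained by group, which was tested over all 35 splits of the libraries into 4 and 4.

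The deposited depth was 36809529 to 42303051 reads per library, with 4 libraries per group. What depth and the spread between replicates each contributed to the precision was not tested. The median standard error of a log2 change was 0.041 for genes of at least 100 CPM, 0.054 from 10 to 100 CPM, 0.11 from 1 to 10 CPM and 0.26 under 1 CPM. Reads without molecular identifiers are not independent molecules, so limits from counts of 0 cover counting error only. The edgeR step was tested on data simulated from the means, depths and abundance trend of the dispersion of this comparison. Of 13740 simulated genes, 200 had been changed, and 13660 genes passed the expression filter. Of the changed genes among these, the step recovered 95.5% at 1 on the log2 scale, 85.1% at 0.5 and 35.4% at 0.25. It made 3 false calls there, and 0 calls when no gene was changed. The simulated genes varied independently and had no dispersion of their own. Few were changed, against an estimate of 38.6% of tested genes in the data. These rates therefore describe the simulation and can differ in the data.

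Within a group, each pair of libraries was compared by a chi-square statistic over genes. It was 3.56 to 20.4 times its degrees of freedom, so no 2 libraries were a single library deposited again. This does not say whether they were separate cultures, which the labels leave open; each was counted as 1 replicate because the labels list it as a separate sample. Both groups hold replicate numbers 1, 3 and 4, but the labels do not say that a number marks a shared batch or day, and the libraries were treated as unpaired. The labels give no sequencing batch or date. Alternatives set before the data were examined were RLE scaling, library size only, DESeq2 1.42.0, limma-voom, no filter or a filter of 1 CPM in 4 libraries, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a minimum change, a test against a minimum change, and leaving out each library in turn. Alternatives chosen after seeing the data were cyclic loess scaling, thinning to equal depth, removal of the 50 most counted genes, and fits of 6 libraries.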

Results

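Messenger RNA was sequenced from primary carotid artery endothelial cells, the cells that line the inner wall of the artery supplying the head, taken from 1 juvenile male olive baboon (Papio anubis). The cells had been cultured for 24 h without flow on polyurethane that was either planar or moulded into parallel ridges and grooves 3 µm wide and 1 µm deep. Grooves of this kind are used to make endothelial cells elongate and align with the ridges, as they do under blood flow. The submitters' stated interest was the effect of elongation and alignment on the transcriptome; the values here compare the substrates, and cell shape was not among the measurements used here. Each substrate had 4 libraries, numbered 1, 2, 3 and 4 on the planar substrate and 1, 3, 4 and 5 on the micropatterned one. All cells came from the same animal, and the labels do not say whether the libraries of a group were separate cultures. The p-values therefore set the substrate difference against the spread between these libraries and carry no information on the spread between animals. If the libraries of a group shared a culture, the p-values would not cover the spread between cultures either.

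The planar libraries held 38338036 to 42303051 counted reads, with a mean of 40732806 ± 1841092 (SD, n = 4). The micropatterned libraries held 36809529 to 37778834, with a mean of 37466064 ± 452077 (SD, n = 4). Every planar library was deeper than every micropatterned one, which gave p = 0.0286 in a two-sided exact permutation test over 70 arrangements, the smallest value this design allows, and an adjusted p of 0.0857 over the 3 library measures tested. The number of genes with at least 10 reads was 13808 ± 53.4 (SD, n = 4) on the planar and 13776 ± 55.5 (SD, n = 4) on the micropatterned substrate, a difference within the replicate spread (exact permutation p = 0.4, adjusted p = 0.486). The 10 most counted genes took 4.97% ± 0.0398 (SD, n = 4) of the planar and 5.00% ± 0.0834 (SD, n = 4) of the micropatterned reads (exact permutation p = 0.486, adjusted p = 0.486). A count of 0 allowed a level of up to 0.0708 to 0.0812 CPM depending on the library (CPM, counts scaled to the TMM-adjusted library size). The files name genes by Ensembl identifier alone and pair none of them with a symbol, so genes are described here by number, abundance and size of change.

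Many genes differed in transcript level between the substrates, most of them by small amounts. Of 13740 genes tested, 1789, or 13.0%, differed between substrates, 900 of them higher and 889 lower on the micropatterned substrate (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Tested against a change of 0.2 on the log2 scale in place of 0, 186 genes were called, 121 higher and 65 lower. The median change among the 1789 was 1.19-fold, or 0.25 on the log2 scale, with an interquartile range of 0.19 to 0.37. The median was 0.29 among the genes that rose and -0.22 among those that fell. Log2 changes of the called genes ranged from -2.14 to 1.71. The coefficient of variation between replicates beyond counting error was 5.64%. Without an adjustment for multiple testing, 4010 genes had a p under 0.05, and the p-value distribution gave an estimate of 38.6% of tested genes with some difference.

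**Figure D1:**
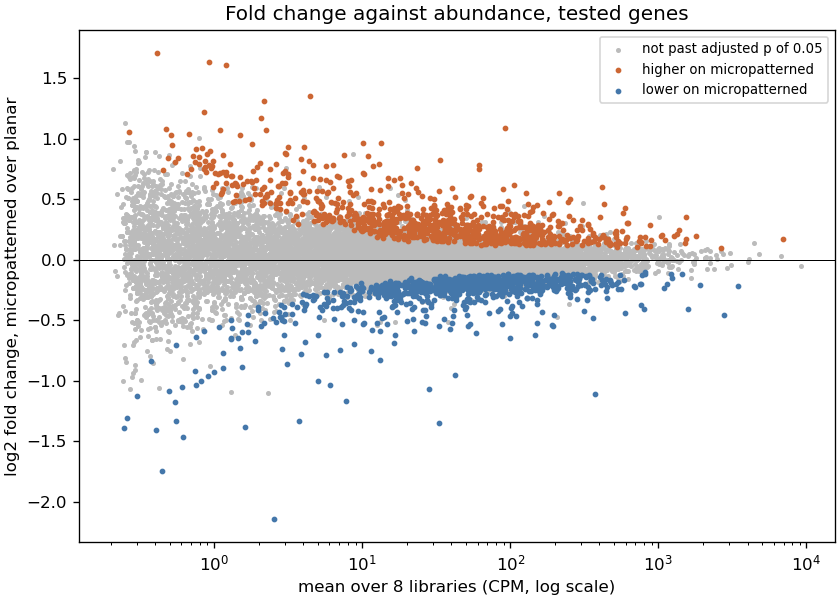
Log2 fold change of micropatterned over planar for each tested gene, against its mean abundance over the 8 libraries in CPM (log scale). Orange points are the 900 genes called higher, blue points the 889 called lower and grey points the genes not past the threshold; most called genes lie close to 0.

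Large changes were few. The change reached 1.5-fold in 179 genes, 122 of them higher and 57 lower, so 90.0% of the called genes changed by less than that. Across the fits that left out 1 library each, the number reaching 1.5-fold lay between 121 and 231, with higher genes outnumbering lower ones in each. The higher or the lower genes moved in number by over 1.5 times in 2 of these fits. There, 78 genes were higher without micropatterned replicate 5, and 36 were lower without micropatterned replicate 1. The number reaching 1.5-fold was 85, 58 higher and 27 lower, among genes whose change was tested against 0.2 on the log2 scale. It was 67 (46 higher, 21 lower) with the replicate number as a block and 80 (51 and 29) in the 6 libraries of shared replicate numbers. With limma-voom it was 181 (123 higher, 58 lower), and 162 (98 and 64) after cyclic loess scaling, chosen after seeing the data. A 2-fold change was reached by 36 genes, 15 higher and 21 lower, and 19 of these averaged under 1 CPM. No tested gene was switched on or off: 10 genes had reads in all 4 libraries of one group and in none of the other, each with at most 10 reads over the 8 libraries, and none of these was abundant enough to be tested.

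Changed genes lay at all abundance levels, and the share called was higher among more abundant genes. Among genes averaging at least 100 CPM, 460 of 2328 were called, or 19.8%, of which 209 were higher and 251 lower, and the smallest change called was 0.098 on the log2 scale. Between 10 and 100 CPM, 989 of 6797 genes were called, or 14.6%, of which 476 were higher and 513 lower. Between 1 and 10 CPM, 290 of 3098 were called, or 9.36%, of which 184 were higher and 106 lower. Under 1 CPM, 50 of 1517 were called, or 3.30%, of which 31 were higher and 19 lower, and no change below 0.59 on the log2 scale was called there. Together, the genes called higher rose from 86513 ± 1695 CPM (SD, n = 4) on the planar to 100884 ± 3408 CPM (SD, n = 4) on the micropatterned substrate. The genes called lower went from 103033 ± 1786 CPM (SD, n = 4) to 87950 ± 3556 CPM (SD, n = 4). These sums describe genes chosen by the same test and are not independent evidence of a difference.

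For most tested genes that were not called, the confidence interval left out a large change. Each interval stands for 1 gene, without adjustment for the number of genes. Of the 11951 such genes, 10289, or 86.1%, had a 95% confidence interval of the fold change within 1.5-fold in either direction (limma-voom), and 11585, or 96.9%, had one within 2-fold. In 2615 of the tested genes, or 19.0%, the 4 libraries of one group all lay above the 4 of the other. When the groups do not differ, the share expected on average is 2.86%. Genes vary together, so the share in a single data set can lie far from that average. The called genes made up 1602 of the 2615.

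Leaving out 1 library at a time gave 980 to 2244 changed genes. The count fell by over 1.5 times without planar replicate 2 (980 genes), planar replicate 3 (1104), micropatterned replicate 1 (1134), micropatterned replicate 4 (1073) or micropatterned replicate 5 (1152). In all 8 of these fits, 818 of the 1789 genes were past the threshold. No called gene changed direction in any of them. In 1602 of the 1789 the libraries of the 2 groups did not overlap, and leaving out 1 library can hardly reverse those. The unchanged directions therefore add little support. With the replicate number as a block, 458 genes were called, 267 higher and 191 lower. The 6 libraries of shared replicate numbers gave 617 without a block, 359 higher and 258 lower, a fit chosen after seeing the data.

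At most 2 genes per direction are named, those with the largest change among called genes averaging at least 1 CPM. ENSPANG00000025525 rose from 0.590 ± 0.185 CPM (SD, n = 4) on the planar to 1.82 ± 0.525 CPM (SD, n = 4) on the micropatterned substrate, a log2 change of 1.61 ± 0.24 (SE) with an edgeR adjusted p of 0.00116. ENSPANG00000015383 rose from 2.49 ± 0.321 CPM (SD, n = 4) to 6.35 ± 0.741 CPM (SD, n = 4), a log2 change of 1.35 ± 0.12 (SE) with an edgeR adjusted p of 2.13e-05. ENSPANG00000000700 fell from 2.32 ± 0.831 CPM (SD, n = 4) to 0.888 ± 0.146 CPM (SD, n = 4), a log2 change of -1.38 ± 0.26 (SE) with an edgeR adjusted p of 0.00505. For each of these 3 genes the call held under each of the 22 alternative fits. In these 3 genes, and in the named gene that follows, the libraries of the 2 groups did not overlap. The same held for 1602 of the 1789 called genes, so it adds no support to these calls. ENSPANG00000024869 had the largest decrease of any called gene, from 4.15 ± 2.47 CPM (SD, n = 4) to 0.940 ± 0.419 CPM (SD, n = 4), a log2 change of -2.14 ± 0.51 (SE) with an edgeR adjusted p of 0.0280. Its planar libraries ranged from 1.74 to 7.43 CPM, the highest being planar replicate 1. The direction held in all 22 alternatives, which adds little for a gene without overlap. Log2 changes were -2.45 to -1.50 and adjusted p 0.0012 to 0.287, and the call was lost in 11 of the 22. Leaving out planar replicate 2 gave an edgeR adjusted p of 0.0754, micropatterned replicate 1 gave 0.0708, micropatterned replicate 4 gave 0.0541 and micropatterned replicate 5 gave 0.13.

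**Figure D2:**
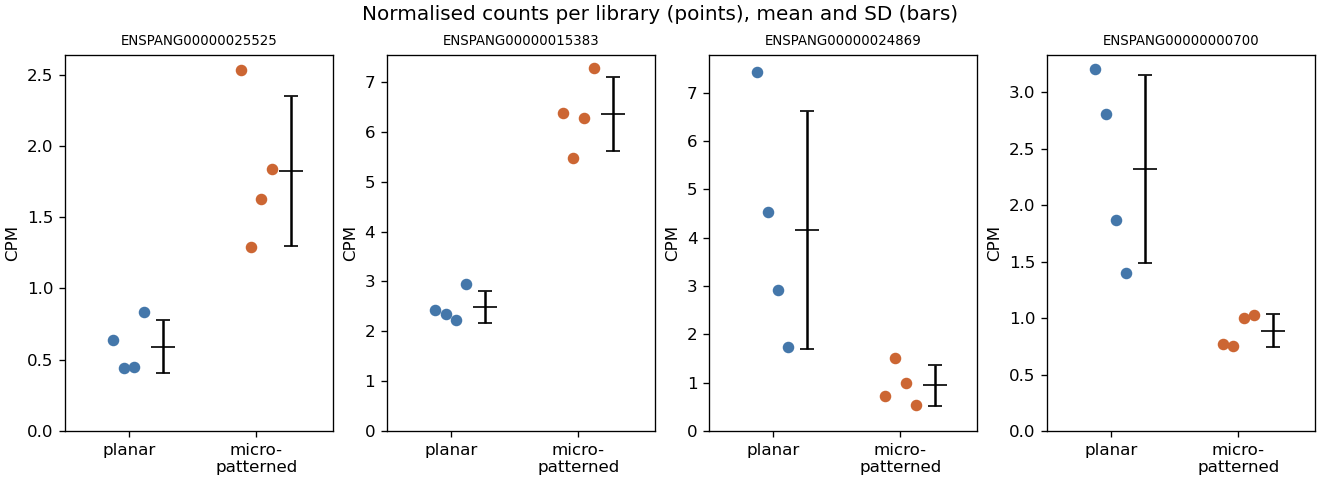
Normalised counts (CPM, linear axis from 0) of the 4 named genes in each library, planar in blue and micropatterned in orange, with the group mean and SD as black bars. The planar libraries of ENSPANG00000024869 spread from 1.74 to 7.43 CPM, while ENSPANG00000015383 separates the groups by more than either group's spread.

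The substrates also separated whole transcriptomes. Group explained 31.8% of the squared distance between libraries over the 500 most variable genes. Any split explains some share by this measure, so 31.8% is not the share due to the substrate alone. None of the 34 other splits of the 8 libraries explained more than 23.4%, which gave p = 0.0286 in an exact permutation test over 35 splits, the smallest value the design allows. On the first principal component, which held 36.9% of the variance, the planar libraries scored from -12.2 to -3.51 and the micropatterned ones from 1.84 to 10.6. Planar replicate 1 and micropatterned replicate 5 lay at its ends. On the second component, with 16.9% of the variance, planar replicate 1 scored 8.58 and the other planar libraries -6.05 to -4.30. Without planar replicate 1 and micropatterned replicate 5, a choice made after seeing these scores, edgeR called 1792 genes, of which 1352 were among the 1789.

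**Figure D3:**
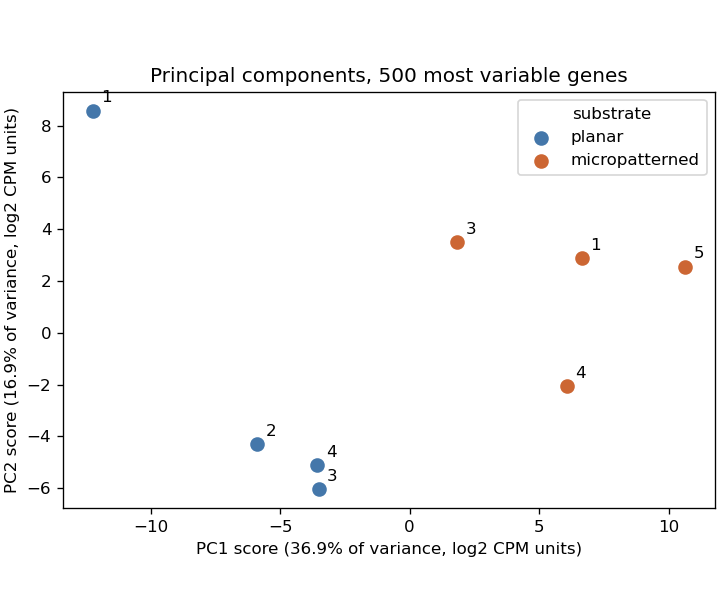
Scores of the 8 libraries on the first and second principal components of log2 CPM over the 500 most variable genes, with replicate numbers beside the points. Planar libraries (blue) lie at -3.51 or lower on the first component and micropatterned libraries (orange) at 1.84 or higher; planar replicate 1 stands apart on the second.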

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

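The 4 tests of the spread within groups, and the thinning, the removal of the most counted genes and the cyclic loess scaling, were chosen after the results they bear on were seen.

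Planar replicate 1 scored 8.58 on the second principal component, while the other 3 planar libraries lay between -6.05 and -4.30, farther apart than Dixon's 95% limit for 4 values allows. This was 1 of 20 such comparisons, and chance gives about 1 in 20. The chi-square statistic per degree of freedom was 10.9 to 20.4 for pairs holding planar replicate 1. It was 3.56 to 4.66 for the other planar pairs and 4.09 to 15.2 for the micropatterned pairs. Planar replicate 1 had a mean distance of 18.4 to the libraries of its group, against 15.6 to 16.1 for the others, within Dixon's limit. These measures share the same counts and are not independent of the score.

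The libraries of each group were spread along the first principal component, and whether the 2 spreads are related was asked across 13740 genes. Micropatterned replicate 3 minus 5, the pair with the highest value, correlated with planar replicate 1 minus the other planar libraries at r = 0.27; over the 6 micropatterned pairs r ran from -0.16 to 0.27, and among the 5971 genes with a mean log2 CPM of at least 5 from -0.39 to 0.53. The r of 0.27 became 0.28 without the 500 most variable genes, which argues against those genes making it. An axis common to both substrates and a different extent of the substrate response in micropatterned replicates 3 and 5 stay open as hypotheses. The second gave r = -0.27 against the response measured in the other libraries without planar replicate 1. Over the 6 pairs this r ran from -0.27 to 0.20. For planar replicate 1 the corresponding r was -0.096, which did not reach the bound of -0.1 set for it. It lay too close to that bound to argue against a different extent there. Genes vary together and no chance value of r was available, so neither hypothesis can be told apart from chance.

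The other pattern weighed is the number of changed genes. Of the 35 splits of the libraries only the real one called 1789 genes, and the highest of the other splits called 1. This is the smallest share the design allows, so it argues against chance assignment of libraries to groups without excluding it. The other splits mix both substrates on each side, which can widen the spread within a side. Their counts are therefore not those of groups that do not differ. The greater depth of the planar libraries was argued against by thinning all libraries to the smallest total, which gave a median of 1741.5 genes over 10 draws. A few dominant genes shifting the scale were argued against by removing the 50 most counted genes, which left 1773 calls against 1778 among the same genes before, and a trend of fold change with abundance by cyclic loess scaling, which gave 1737 voom calls against 1755. A bias from GC content or transcript length cannot be told apart from an effect of the substrate, because 0 of the tested genes had either value; a batch that coincided with the substrate also stays open, since the labels give no dates.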

How the results depend on the processing

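Against 1789 changed genes, RLE scaling, library size only, DESeq2, limma-voom, both filters and 1 surrogate variable gave 1755 to 2104, all within 1.5 times. No called gene changed direction under any alternative, which the selection of these genes in the same counts made likely beforehand. The count was 252 with a log2 change of at least 0.5 (66.7% higher, against 50.3%), 186 when tested against a change of 0.2 (65.1% higher), and 980 (without planar replicate 2) to 2244 (without micropatterned replicate 3) when 1 library was left out. Of the 1789 genes, 179 reached 1.5-fold, against 67 (46 higher, 21 lower) with the replicate block, 85 (58 and 27) when tested against a change of 0.2 and 80 (51 and 29) in the 6 libraries of shared numbers. With the replicate block, 458 genes were called, and 617 in the same 6 libraries of numbers 1, 3 and 4 without it, a fit chosen after seeing the data. Another 6 libraries, without planar replicate 1 and micropatterned replicate 5, gave 1792, so the count depended on which libraries entered; the cause was not tested. Over all tested genes, the deviations of same-numbered libraries had r of 0.020, -0.11 and -0.0092 for numbers 1, 3 and 4. None correlated best with its own number. Abundant genes were not examined separately and no chance value of r was available, so a shared batch cannot be decided from these values. Group explained 28.0% to 35.6% of the squared distance over the RLE, gene-number and leave-one-out settings, each at the smallest exact p of 0.0286. In those other 6 libraries it explained 32.9%, where 10 splits allow no p below 0.1. The gene list tests and their other settings were not run, since no list could be matched. The smallest change called was 0.59 on the log2 scale under 1 CPM and 0.098 at 100 CPM and over, and what depth contributed to this was not tested.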
